A study of Mus musculus with 2 samples.

How the data were processed

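MicroRNA sequencing, which reads the small RNA fraction of a total RNA sample, was done on kidney tissue of B6NCrl mice on postnatal day 0. The series holds 2 samples. Each was made from the 2 kidneys of 1 pup, and the labels number both pups under the same pregnancy, so both form 1 group of 2 biological replicates, pup 1 and pup 2. The labels state an upper size limit of 30 for the RNA without its unit, and state that sex was not collected.

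The deposited tables hold whole-number read counts per gene, not normalised, for 1973 microRNA genes in each library. Reads were aligned to the mouse assembly mm10 and counted over genes of annotation release M4, per the deposited notes that come with the tables. The aligner, its settings, adapter trimming and quality filters are not given in the sources used here. The leading rows that name no gene carry the names that the STAR aligner uses in its gene count output. The authors' tables give 3 count columns without a header. In both libraries the sum of each column and its row for reads assigned to no listed gene came to the same total, as it does for counts on either strand, on the strand of the gene and on the opposite strand. The column for the strand of the gene was the measurement used here, read from the values. A count belongs to a hairpin gene, so the mature arms of a microRNA were not separated.

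Rows that name no gene stayed out of library sizes and tests. Of 10014956 reads in pup 1 and 6700198 reads in pup 2, multimapping reads took 30.3% and 31.0%, unmapped reads 8.52% and 8.69%, and reads on the strand of no listed gene 2.91% and 2.92%. The last kind includes reads opposite to a listed gene, 121726 in pup 1 and 78841 in pup 2. No read was listed as ambiguous. The remaining 5832192 counts in pup 1 and 3846704 counts in pup 2, 58.2% and 57.4% of reads, are the depth behind every value. For a gene whose hairpin shares no stretch with another, a count of 0 allows up to 3 counts, which is 0.514 CPM in pup 1 and 0.780 in pup 2. Such floors, and the Wilson intervals below, cover counting error only, because reads without molecular identifiers are not independent molecules.

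Gene identifiers were matched without their version to GENCODE release M21, which uses the same assembly as the tables. Of the 1973 genes, 1894 matched, 1815 of them with the same version, and the 79 others held 1 count in both libraries together. Symbols, coordinates (counted from 1) and hairpin sequences came from that release. Host genes were sought on the same strand, without microRNA, snoRNA, snRNA, scaRNA, tRNA, rRNA, misc_RNA and TEC genes. A place in an exon means that some transcript of the host gene has an exon there, while others may have an intron. Genes whose hairpin shares a stretch of 22 bases with a hairpin elsewhere in the genome were marked, since reads of such genes can match more than 1 place.

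Counts were scaled to CPM with the total over all named genes of a library, and levels are given as mean ± SD over the 2 pups. Shares of counts were summed over 27 gene lists of families, genomic clusters and cell type markers. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The genes named are the 25 with the highest mean, the 4 highest members of each list with any member at 0 in both pups, and the 10 largest log2 ratios between pups among genes with a mean count of at least 100 that passed the test. Other genes named were chosen after their values were seen. With 2 pups in 1 group no test between groups exists, and the smallest two-sided exact sign test p is 0.5.

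The pups were compared across genes with a mean count of at least 10, by Pearson's r and Spearman's rho of log2(CPM + 1) and by a chi-square test of both count columns. For each gene an exact two-sided binomial test compared both counts given their sum and the TMM effective library sizes of edgeR, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test compares the reads of 2 libraries and not conditions, and it covers counting error only. Log2 ratios are pup 2 over pup 1 with a prior count of 0.5. The spread between pups was also estimated as edgeR's common dispersion, with both pups as 1 group. For each list with at least 3 tested genes, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 10 bins.

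The binomial test was tested on simulated data with known changes and counting error alone. Among the 325 simulated genes past the count filter it called 0.4% of 226 unchanged genes, 69.6% of 46 genes changed 1.5-fold and 92.5% of 53 genes changed 3-fold. These rates hold where counting error is the only noise, and the pups differed by more than that, so they are not error rates for the pups. A simulated biological coefficient of variation of 10% was estimated as 10.1%. Alternatives were library totals and DESeq2 size factors in place of TMM, thresholds of 1 and 100 CPM for detection, no filter and a mean count of at least 100, pseudocounts of 0.1 and 10, totals without the most abundant gene, removal of identical copies, counts on either strand, an edgeR exact test with the estimated dispersion, and each pup left out. Counts from the opposite strand given to the microRNA they overlap, and the 22-base rule for copies, were added after seeing the data. R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Other ages and tissues were not analysed here.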

Results

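MicroRNAs were counted in whole kidney tissue from 2 newborn B6NCrl pups of the same pregnancy, at postnatal day 0. The tables gave 5832192 counts in pup 1 and 3846704 counts in pup 2 on the strand of 1973 microRNA genes. The design holds 1 tissue at 1 age, so the comparisons are those between microRNA genes and families within the kidney and that between the pups. Values are CPM, which are counts scaled by the library total, or percent of counts, given as mean ± SD with n = 2 pups unless stated.

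Mir10a, a microRNA of the Hoxb cluster, had the highest count of the microRNA genes in the newborn kidney at 154437 ± 4642 CPM, which is 15.4% ± 0.464 of all counts. Multimapping reads, 30.3% and 31.0% of reads in the pups, are listed apart from gene counts, so ranks and shares here hold among reads counted for a gene. Next came Mir126a, known from endothelial cells, at 79588 ± 10777 CPM. Mir10b of the Hoxd cluster followed at 68835 ± 1576, Mir335 of the imprinted gene Mest at 54955 ± 1919, and Mirlet7g at 51758 ± 1572 CPM. The gap between Mir10a and Mir126a was larger than the SD of either gene, and Mir10a exceeded Mir10b 2.25-fold in pup 1 and 2.23-fold in pup 2. Such an SD covers the spread between the pups only. How many reads a molecule of each microRNA yields was not measured, so ranks, shares and ratios between genes are those of reads. Mir322, an X-linked microRNA related to the miR-15/16 family, reached 43791 ± 436 CPM, and Mir143, known from smooth muscle, reached 36917 ± 2966.

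On mm10, Mir10a (ENSMUSG00000065519.1) lies on the plus strand of chromosome 11 from 96317165 to 96317274, with no host gene of the types considered on that strand. Mir126a (ENSMUSG00000065540.1) lies on the plus strand of chromosome 2 from 26591357 to 26591429, where some transcript of Egfl7 has an exon. Mir10b (ENSMUSG00000065500.2) lies on the same strand and chromosome from 74726070 to 74726137, in introns of Hoxd3 and Hoxd4. Mir335 (ENSMUSG00000065501.1) lies in an intron of Mest on the plus strand of chromosome 6, from 30741299 to 30741396. Mirlet7g (ENSMUSG00000065440.1) lies in an intron of Wdr82 on the plus strand of chromosome 9, from 106178840 to 106178927. Mir322 (ENSMUSG00000065418.1) lies on the minus strand of chromosome X from 53054255 to 53054349, also with no such host gene on its strand.

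Among the remaining abundant genes, Mirlet7i stood at 38857 ± 3156 CPM, Mir30e, in an intron of Nfyc, at 31966 ± 3330, and Mir26b, in an intron of Ctdsp1, at 29711 ± 1226. Mir130a had 29536 ± 372, Mir99a 25516 ± 3323, Mir23b 24272 ± 65.8, and Mir196b, in an exon of some Hoxa9 transcript, 22510 ± 1054 CPM. Mir30a had 21077 ± 1872 and Mir17 19249 ± 1401 CPM. Mir429 of the epithelial miR-200 family had 17174 ± 27.8 CPM, Mir21a, in an untranslated region of Vmp1, 12810 ± 1139, and Mirlet7d 12379 ± 51.5. Levels of Mir22, Mir23a, Mir99b, Mir20a, Mir200b and Mir93 ran from 11665 ± 168 CPM in Mir22 to 6996 ± 612 in Mir93. Neighbours in this ranking were often closer than their SD, as for Mir26b and Mir130a, and their order is then not resolved by 2 pups.

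**Figure D1:**
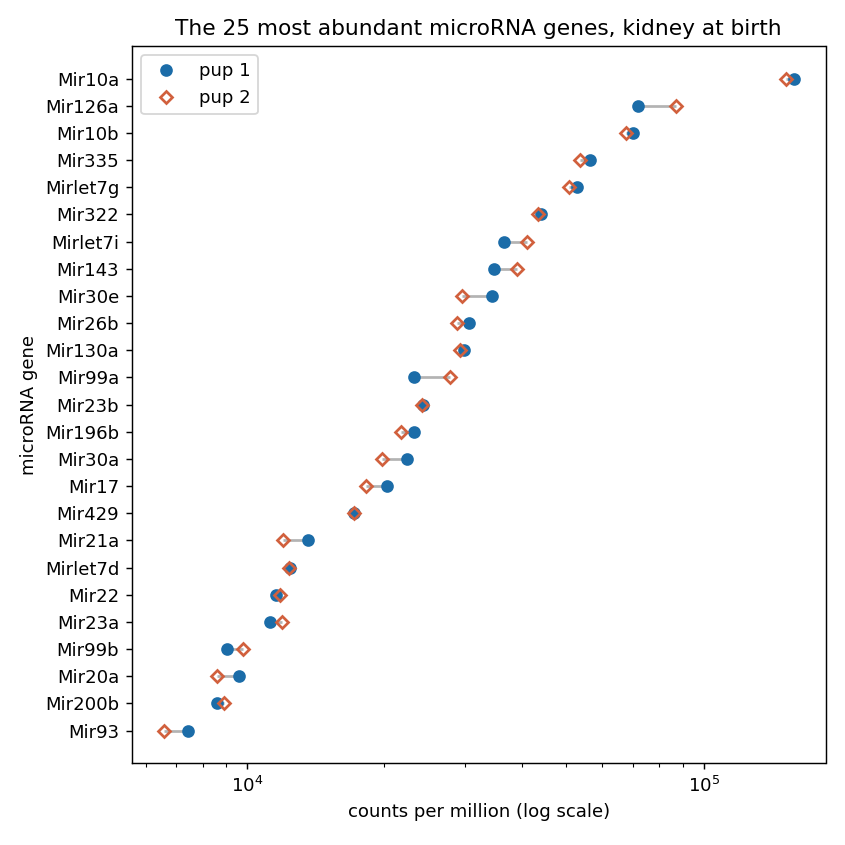
CPM (log axis) of the 25 most abundant microRNA genes in each pup, with a filled circle for pup 1, an open diamond for pup 2 and a line joining them. Mir10a stands highest in both pups, at a mean of 154437 CPM, and Mir93 closes the list at 6996.

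The 10 most abundant genes held 59.1% ± 0.220 of counts and the 25 most abundant 83.3% ± 0.032, while 8 genes sufficed for 50% and 41 genes for 90% of counts. At 10 CPM or more in both pups, 246 microRNA genes were detected, and 73 of them reached 1000. At least 1 count in both pups was found for 526 genes, and 1277 genes had 0 counts in both, which allows up to 0.514 CPM of counted reads in pup 1 and 0.780 in pup 2. Of these genes 766 share 22 bases with another hairpin, and for them a count of 0 does not bound the level. For the 79 genes without a match in release M21 no hairpin sequence was at hand, so sharing is not known for them.

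The listed Hox cluster microRNAs, 5 genes of the miR-10 and miR-196 families, formed the largest listed group among counted reads, with 24.7% ± 0.723, of which Mir10a, Mir10b and Mir196b supplied nearly all, and Mir196a-2 and Mir196a-1 stood at 1483 ± 44.5 and 32.3 ± 4.08 CPM. Mir615, in an intron of Hoxc5, is outside that list and had 1480 ± 143 CPM. The let-7 family, known for its part in developmental timing, followed with 11.8% ± 0.155 over 10 genes, led by Mirlet7g, Mirlet7i, Mirlet7d and Mir98 (5713 ± 2.13 CPM), while Mirlet7e and Mirlet7f-1 have no row of their own in the tables used here. Since 5 of the 10 let-7 genes share 22 bases with another hairpin, their share leaves out any of their reads that were listed as multimapping. Mir126a came next with 7.96% ± 1.08. The miR-30 family held 5.92% ± 0.545, led by Mir30e, Mir30a, Mir30d (5510 ± 294 CPM) and Mir30b (377 ± 36.7). The distance between the Hox group and the let-7 family, and that between the let-7 family and Mir126a, was larger than the SD of either group in counted reads. That order rests on Mir10a. Without Mir10a in list and total the order turned over, with the Hox share at 10.98% and the let-7 share at 13.997%.

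MicroRNAs of the imprinted genes Igf2, H19, Mest and Gnas held 5.90% ± 0.217 of counts. Mir335 made up most of that share, followed by Mir296 (2429 ± 262 CPM), Mir298 (1283 ± 0.10) and Mir483 of Igf2 (346 ± 9.32). The imprinted Dlk1-Dio3 microRNAs were many and mostly of low level, with 29 of 37 counted genes at 10 CPM or more in both pups and a joint share of 0.782% ± 0.103. Another 6 genes of that list have no row of their own. With opposite-strand reads given to missing microRNAs, an alternative chosen after seeing the data, the share was 0.889%. The highest counted Dlk1-Dio3 genes were Mir411 (1912 ± 458 CPM), Mir127 (1053 ± 145.4), Mir379 (986 ± 155) and Mir487b (635 ± 42.4), and Mir654 had 0 counts in both pups. The X-linked cluster of miR-322 and miR-503 held 4.83% ± 0.0241, with Mir322 at 57.1 ± 1.57 times the level of Mir503. Mir351 and Mir542 had 2904 ± 238 and 725 ± 3.17 CPM. That share leaves out Mir450-1 (86 counts in pup 1, 70 in pup 2) and Mir450-2 (65 and 40), since the list holds them under other symbols.

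The miR-17~92 cluster and its paralogs, known from proliferating progenitor cells, held 4.66% ± 0.290, led by Mir17, Mir20a (9118 ± 719 CPM), Mir93 and Mir106b (5337 ± 25.2). The miR-99/100 and miR-125 genes held 4.22% ± 0.419, led by Mir99a, Mir99b (9421 ± 544), Mir100 (3546 ± 345) and Mir125a (3215 ± 36.2 CPM). The miR-232724 clusters held 3.93% ± 0.0664, with Mir23b and Mir23a far above Mir27b (2943 ± 187 CPM) and Mir27a (321 ± 39.4). Mir24-1 of these clusters has no row of its own. The miR-26 family held 2.98% ± 0.122, nearly all from Mir26b, since Mir26a-2 and Mir26a-1 had 60.6 ± 4.42 and 22.5 ± 0.50 CPM. The miR-15/16 family held 1.14% ± 0.047, or 1.24% with opposite-strand reads given to missing microRNAs, chosen after seeing the data. It was led by Mir15a (4283 ± 297 CPM), Mir16-1 (2731 ± 141), Mir195a (2071 ± 23.1) and Mir15b (1624 ± 24.1). The miR-181 family held 0.816% ± 0.0431, led by Mir181c (3848 ± 82.8 CPM), Mir181d (2190 ± 298), Mir181a-1 (1493 ± 95.8) and Mir181b-2 (571 ± 154).

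Smaller shares belonged to the cluster of miR-183, miR-96 and miR-182 with 0.376% ± 0.0218, led by Mir182 at 2076 ± 204 CPM, with Mir183 at 996 ± 12.4 and Mir96 at 688 ± 2.10. The miR-29 family held 0.0212% ± 0.0004, with Mir29c and Mir29a at 119 ± 3.48 and 91.5 ± 7.40 CPM and Mir29b-2 and Mir29b-1 below 1. Mir204 had 378 ± 28.7 CPM and Mir211 1.38 ± 0.48, for a share of 0.038% ± 0.0028. Reads of hairpins that share 22 bases with another hairpin, such as Mir26a-2, Mir16-1, Mir181a-1, Mir196a-2 and Mir29b-1, can match more than 1 place, so their levels are uncertain. The listed genes with an identical mature copy elsewhere, without Mir450-1 and Mir450-2, held 1.68% ± 0.0217 of counts together.

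Of the lists tied to cell types, the endothelial Mir126a (7.96% ± 1.08) was followed by Mir143, Mir145a and the miR-199 and miR-214 genes of mesenchyme and smooth muscle with 4.24% ± 0.301 and by the epithelial miR-200 family with 3.16% ± 0.0077. Mir143 stood at 33.7 ± 0.322 times the level of its neighbour Mir145a, and Mir214 and Mir199b had 4141 ± 15.1 and 214.5 ± 16.5 CPM. In the miR-200 family, Mir429 and Mir200b (8730 ± 219.6 CPM) stood above Mir200c (3671 ± 128) and Mir200a (1373 ± 25.8). The miR-192, miR-194 and miR-215 genes, known from the mature proximal tubule, held 0.0872% ± 0.0034, with Mir192 at 563 ± 54.8, Mir194-2 at 296 ± 18.5, Mir215 at 10.1 ± 1.45 and Mir194-1 at 3.70 ± 0.83 CPM. In counted reads, the miR-200 share exceeded that of the miR-192, miR-194 and miR-215 genes by far more than the SD of either list. Mir194-1, Mir194-2 and the miR-199 genes share a stretch of hairpin with another hairpin, while no miR-200 gene does. Levels and shares of the sharing genes leave out any of their reads listed as multimapping. With identical copies removed, the shares were 3.21% for the miR-200 family and 0.0583% for Mir192 and Mir215. MicroRNAs tied to hypoxia, p53 and injury held 1.40% ± 0.114, nearly all from Mir21a, while Mir34c (539 ± 61.0 CPM), Mir210 (351 ± 65.2) and Mir34a (321 ± 2.57) were lower.

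In counted reads, markers of blood cells and of other tissues were low. Leukocyte genes held 0.0704% ± 0.0045, with Mir223 at 298 ± 26.1, Mir155 at 257 ± 6.83, Mir146 at 118 ± 9.16 and Mir150 at 30.4 ± 2.57 CPM, and Mir142 has no row of its own in the tables used here. Reads opposite to Mir142b, at the place of Mir142, came to 367 ± 3.58 CPM, and giving such opposite-strand reads to the microRNA they overlap, an alternative chosen after seeing the data, put the leukocyte share at 0.105% and the let-7 share at 12.01%. The erythroid genes Mir451a, Mir144 and Mir486 held 0.0241% of counts in pup 1 (95% Wilson interval 0.0229 to 0.0254) and 0.0099% in pup 2 (0.0089 to 0.0109). Endocrine and pancreas genes held 0.013% ± 0.0016, nearly all from Mir375 at 129 ± 16.4 CPM, with Mir217 and Mir216b below 1 and Mir216a at 0 counts. The liver marker Mir122 had 50.6 ± 9.00 CPM, a share of 0.0051% ± 0.0009. Neural genes held 0.0027% ± 0.0001, led by Mir137 (16.9 ± 1.10 CPM) and Mir153 (7.80 ± 0.37), and Mir124a-1, Mir124a-2 and Mir124a-3 had 0 counts. Genes of pluripotent cells held 0.0014% ± 0.0001, led by Mir293 (4.91 ± 0.33 CPM), with Mir290a at 0 counts. Striated muscle genes held 0.0009% in each pup, led by Mir206 (4.78 ± 0.51 CPM), and Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b had 0 counts in both. The Mir124a genes, Mir1a-1, Mir133a-1 and Mir133a-2 share their sequence with a copy, so a count of 0 does not bound their level. Mir9-2 and Mir9-3 also share a stretch with another hairpin, and Mir486 is among the genes listed with an identical mature copy. Mir486b, Mir9-1 and Mir1a-2 were not counted in their lists. Shares of the erythroid, neural and striated muscle lists thus leave out any reads of these genes listed as multimapping.

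**Figure D2:**
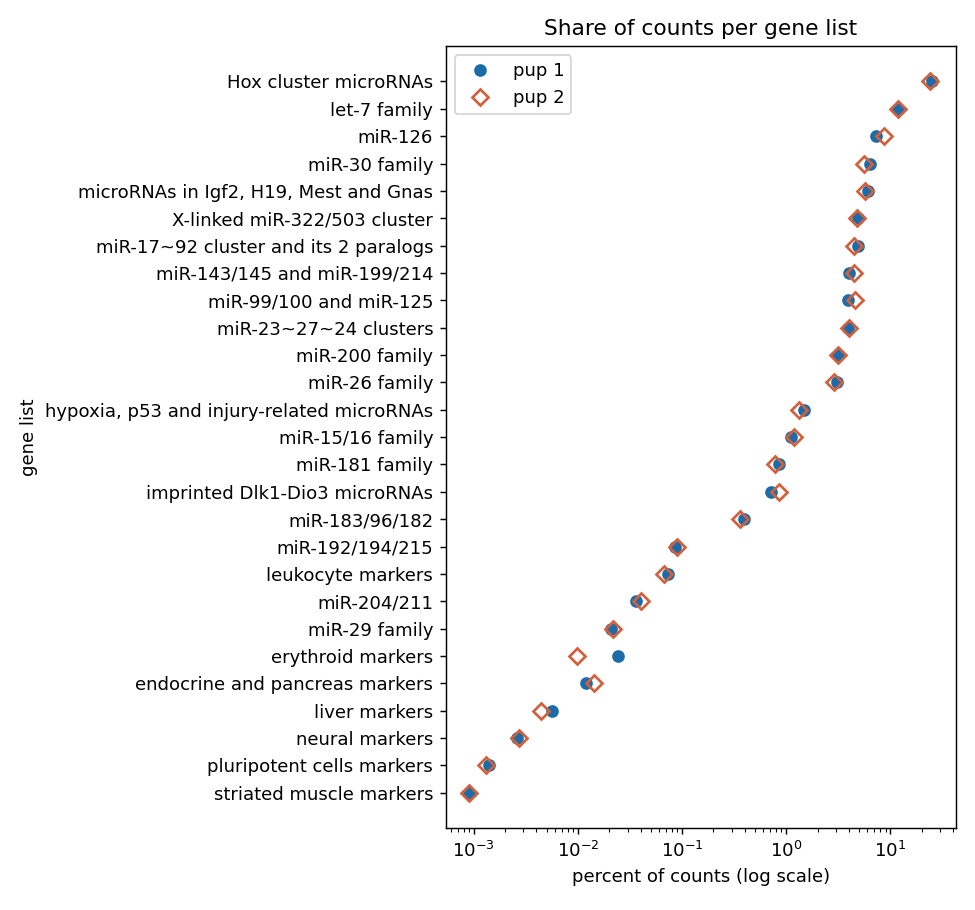
Percent of counts (log axis) held by each of the 27 gene lists in pup 1 (filled circles) and pup 2 (open diamonds). The listed Hox cluster microRNAs stand highest at a mean of 24.7% and striated muscle genes lowest at 0.0009%. As a ratio, which the log axis shows, the erythroid list has the widest gap between pups, 0.0241% against 0.0099%.

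Between the pups, Mir451a, a microRNA of red blood cells, differed most among the genes named by the rule, with 1213 counts in pup 1 and 206 in pup 2. Its log2 ratio of pup 2 over pup 1 was -1.98 (95% counting interval -2.20 to -1.76, adjusted p = 5.8e-97 by the exact binomial test). Mir144, made from the same genomic cluster, went the other way at 0.39 (0.08 to 0.70), with 188 counts in pup 1 and 165 in pup 2. Higher in pup 2 were also Mir411 (0.47), Mir369 (0.46) and Mir431 (0.39) of the Dlk1-Dio3 region and Mir181a-2 (0.41). Lower in pup 2 were Mir181b-2 (-0.58), Mir362 (-0.43), Mir671 (-0.43) and Mir122 (-0.38).

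In all, 109 of 324 tested genes passed the exact binomial test with Benjamini-Hochberg adjustment, 41 higher and 68 lower in pup 2. Abundant genes passed with small ratios. Mir126a was higher in pup 2 with a log2 ratio of 0.26 and Mir99a with 0.25, while Mir30e (-0.23), Mir30a (-0.20) and Mir21a (-0.20) were lower. That test knows only counting error, and an edgeR exact test with the dispersion of the pups called 1 gene, Mir451a. Each side of both tests is 1 library, and that dispersion was estimated from the same difference between the pups, so the edgeR test is no independent check of any gene.

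Gene lists were next compared for a joint shift between the pups. The Dlk1-Dio3 genes were higher in pup 2, with a median log2 ratio of 0.11 over 35 genes, at percentile 99.89 of matched random lists. Of these genes 7 passed the test as higher and 0 as lower, also when adjusted over the list alone, among them Mir411, Mir369, Mir431, Mir379 (0.30) and Mir127 (0.26). The list's share was 0.710% of counts in pup 1 (95% Wilson interval 0.703 to 0.716) and 0.855% in pup 2 (0.846 to 0.864). The miR-17~92 genes and paralogs were lower in pup 2, with a median of -0.13 over 15 genes at percentile 1.72, and 7 passed as lower, among them Mir93 (-0.20), Mir20a (-0.18) and Mir17 (-0.17), or 8 adjusted over the list alone. The miR-181 genes had a median of -0.18 over 6 genes at percentile 1.20, but went both ways, with 3 lower (Mir181b-2, Mir181d and Mir181c) and 2 higher (Mir181a-1 and Mir181a-2), the same numbers when adjusted over the list alone. The other 16 of 19 lists lay between percentiles 4.42 and 93.4, and members of a list that are transcribed together are not independent, which the random lists do not take into account.

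**Figure D3:**
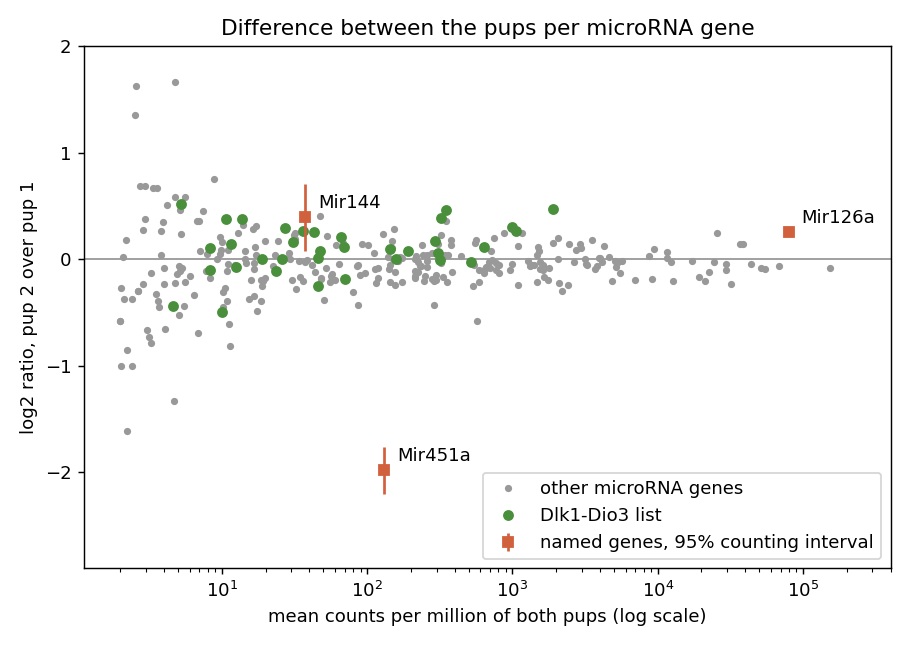
Log2 ratio of pup 2 over pup 1 against mean CPM (log axis) for the 324 tested microRNA genes, with Dlk1-Dio3 genes in green and Mir451a, Mir144 and Mir126a as squares with 95% counting intervals. Mir451a lies at -1.98 and Mir144 at 0.39, and Dlk1-Dio3 genes have a median of 0.11.

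Across the 324 genes, levels in the pups had a Pearson's r of 0.997 and a Spearman's rho of 0.996, over genes that are not independent replicates. The median absolute log2 ratio was 0.15 and its 90th percentile 0.46. With no filter on low counts, over 696 genes, these were 0.46 and 2.16, and rho was 0.915. Over the 324 genes the common dispersion of edgeR gave a biological coefficient of variation of 9.15%. The chi-square statistic of both count columns was 21371 with 323 degrees of freedom, 66.2 per degree, so the tables differed by more than counting noise. Repeat libraries of 1 sample could differ by that much too, and the tables were counted as 2 samples because the labels name 2 pups.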

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

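The tests of the opposite strand, including the limits of 500 opposite reads and 1000 counts, were chosen after the result was seen. Reads on the strand opposite to the annotated gene, which the counts on the strand of the gene leave out, were above the 3-count floor in both pups for 15 genes. Summed over both pups, they came to 107554 reads at Gm25301, 39081 at Gm25927, 24142 at Gm24083, 11861 at Mir497b, 3881 at Gm25252, 3693 at Gm24321, 3551 at Mir142b, 3104 at Mir299b, 1392 at Gm24111 and 1353 at Gm25750. Smaller numbers were 423 at Mir203, 367 at Mir3074-1, 41 at Mir126a, 18 at Mir337 and 17 at Mir708.

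Of the 10 genes with 500 or more opposite reads in both pups, 100% overlap a microRNA gene of the other strand that has no row in the tables used here, although only 32 of the 1973 genes have such a partner. The partners are Mir378a, Mirlet7e, Mir191, Mir497, Mir376a, Mir409, Mir142, Mir299a, Mirlet7f-1 and Mir380, in the order of the reads above. A loss of strand in the library or the alignment is argued against, because the median share of opposite reads was 0% over 123 genes with 1000 or more counts in both pups. That a microRNA gene on the other strand is missing from the tables may therefore account for these reads, and at 11077 ± 242 CPM (SD, n = 2) Mir378a would rank 22nd. Why such genes have no row, and where the reads at Mir203 and Mir708 come from, stays open, and no biological explanation was tested.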

How the results depend on the processing

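The edgeR exact test with the dispersion of the pups was planned, while the 22-base rule for copies and the opposite-strand counts given to missing microRNAs were chosen after seeing the data. Leaving aside 112 values with 1 pup left out and 2 counts of list shifts, which could not move by construction, 126 values kept their side or moved by less than their spread and 57 moved. Neither number measures stability, since others among these values were also fixed or nearly fixed by construction. For example, the median absolute log2 ratio uses a fixed prior count of 0.5 and not the pseudocounts varied here. A change of scaling moves every log2 ratio by the same small amount. Of the 109 genes that passed between the pups with TMM, 1 changed sign with library totals, Mir429 (log2 ratio -0.02 with TMM), and 0 with DESeq2 size factors. The order of the Hox and let-7 lists did turn over. Of 324 genes tested between the pups, 109 passed with TMM (41 higher in pup 2), 97 with library totals (46 higher) and 96 with DESeq2 size factors (43 higher), but 1 with the edgeR exact test, whose dispersion was estimated from the same 2 pups (14 at an unadjusted p under 0.05). That drop is built in, since the difference tested also sets the dispersion. Genes detected numbered 359 at 1 CPM, 246 at 10 CPM and 163 at 100 CPM, by construction, and 251 to 253 at 10 CPM in 1 pup alone. The share of the 10 most abundant genes was 60.1% without identical copies, and without Mir10a in list and total the Hox share was 10.98%, under a let-7 share of 13.997%. Pearson's r was 0.99627 with no filter, 0.99608 with a pseudocount of 0.1 and 0.99842 with a pseudocount of 10, against 0.99703 as reported, and the cause was not tested. With no filter, rho was 0.915 and the median absolute log2 ratio 0.46. Genes sharing 22 bases held 2.18% of counts against 1.68% for the list of identical copies, because more genes count as copies. Removing Mir10a from the total moved 26 of 28 results, removing identical copies 10 of 30, giving opposite-strand counts to missing microRNAs 8 of 28 and counting either strand 6 of 27. The rise of shares outside the Hox list without Mir10a is built in, since a smaller total raises each of them by the same factor within a pup. For means over the pups, leaving out 1 pup says nothing about stability, since each of 2 pups differs from the mean by less than the SD by construction, and percentiles of lists cannot change with 1 scaling factor for every gene. No paired analysis was possible because the series holds 1 group. Depth limits genes under 0.514 CPM in pup 1 and 0.780 in pup 2, and 2 pups limit every statement on spread.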

Other observations

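The tests of hairpin copies and of Mir451a, the run of the cluster test without Mir451a and Mir144, and the cluster test on levels were chosen after the result was seen, while the remaining cluster tests were fixed before. The gene groups of the next paragraph were also picked from the data.

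Outside the fixed lists, which held 89.2% ± 0.0692 of counts (SD, n = 2), Mir130a was the most abundant gene, and the 4 genes of the miR-130 and miR-301 family held 3.55% ± 0.0505. Mir130b stood at 5183 ± 122 CPM, Mir744, in an intron of Map2k4, at 4826 ± 440, Mir151, in an intron of Ptk2, at 4645 ± 84.8, and Mir652, in an intron of Tmem164, at 3957 ± 68.2. Mir139 had 3240 ± 55.9 CPM and Mir140, known from cartilage and lying in an exon of some Wwp2 transcript, 3170 ± 38.9. The 59 genes of the Mir297, Mir466, Mir467 and Mir669 groups in Sfmbt2, a gene imprinted in the mouse, held 0.273% ± 0.0152, with 7 of them at 10 CPM or more in both pups. Both values leave out any reads of these genes listed as multimapping. Chromosome X held 6.87% ± 0.043 of counts, led by Mir322, with 33 genes at 10 CPM or more in both pups. On chromosome 12, the home of the Dlk1-Dio3 region, 36 genes reached that level but held 1.18% ± 0.119.

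In 15 of 15 lists that hold both kinds, hairpins that share 22 bases with another hairpin had a lower median level than the other members, and without the muscle and neural lists this held in 13 of 13. In the miR-26 family, for example, Mir26b stood at 493 ± 56.2 times the level of Mir26a-2 (SD, n = 2), and Mirlet7g at 301 ± 19.5 times that of Mirlet7a-1. This count restates the pattern that prompted it and does not separate its explanations. A candidate explanation is that reads matching more than 1 place were left out at counting. Multimapping reads were 23.99 and 24.71 times the counts of all sharing genes in the pups, but how many of them came from microRNA hairpins is not known. Lower levels of the copies themselves stay open as well, and Mir27a and Mir145a, which share no such stretch, also lie far below their cluster partners Mir23a and Mir143.

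Mir451a was lower in pup 2, at a log2 ratio of -1.98. Scaling is argued against, because the ratio lay at -1.93 (95% counting interval -2.16 to -1.72) relative to the median of the 324 tested genes, a distance that no common factor moves. A like fall of Mir144, which less red blood cell RNA carrying both microRNAs would bring, was not seen. Mir144 stood at 0.39 (95% counting interval 0.08 to 0.70), and Mir486 had only 4 counts in pup 1 and 9 in pup 2. With 1 library per pup and an interval for counting error only, this does not exclude less red blood cell RNA in pup 2. The ratio of Mir451a to Mir144 was 6.45 in pup 1 and 1.25 in pup 2. Red cells rich in Mir451a but poor in Mir144, Mir144 from other cells, and a true difference between the pups stay open and were not tested.

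The hypothesis that microRNA genes of 1 genomic cluster vary together between animals did not meet its bound. The SD of log2 ratios within 36 clusters of 111 genes with a mean count of at least 100 was 0.2548, against 0.261 for genes placed at random (permutation p = 0.41, one-sided). It was 0.41 after a linear trend on GC content was removed and 0.72 without the Dlk1-Dio3 region, so neither of these had a pattern to account for. A p that misses the threshold does not show that clustered genes vary independently, and without Mir451a and Mir144, left out because their values were known, the permutation p was 0.068 (SD 0.1671 against 0.1804). Levels, in contrast to ratios, were closer within clusters than at random, with an SD of log2 CPM of 2.38 against 2.78 (permutation p = 0.0026). That test was not run without the Dlk1-Dio3 region, so how far this region carries it is not known. In the test of ratios, leaving that region out kept 85 of the 111 genes.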
